A study of Mus musculus with 10 samples.

How the data were processed

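RNA from the livers of 10 female mice aged 6 weeks, kept on chow and not fasted per the labels, was hybridised to Affymetrix MG_U74A GeneChips, 1-colour oligonucleotide arrays that report one value per probe set. Each array held the RNA of 1 mouse, so the replicates are animals. The 5 Scd1-null mice were of a mixed 129 and C57BL/6J background and the 5 wild-type mice were C57BL/6J, per the labels, so genotype and strain background differ together.

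The deposited table held intensity values on a linear scale for 10043 probe sets on 10 arrays, as whole numbers of which 1.20% lay below 0. The algorithm by which the authors summarised probe pairs into these intensity values, and any scaling or background step, are not given in the sources used here. The arrays' means, trimmed by 2% at each end, differed by up to 19.6%, so the deposited intensity values had not been brought to a common trimmed mean. Array-to-array correlations lay between 0.961 and 0.985, and no pair of arrays shared most of its values. The other deposited files, 1 per array, hold settings of the hybridisation as text and no expression values. They gave the chip lot, the fluidics module and the time of hybridisation. They also held a comment that evaporation made the amount of cRNA inaccurate for wild-type replicate 3. The fluidics run was derived from those times, with a new run after each gap of over an hour.

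By a rule fixed before the data were examined, arrays whose trimmed means differed by over 1% were quantile normalized. The 66 control probe sets were left out first, which left 9977. Values were then floored at the 25th percentile of all values, an intensity of 351, and taken to log2. A probe set was kept if it lay above the floor on at least 5 of the 10 arrays, whichever they were. This kept 7569 probe sets and left out 2408. Differences close to the floor are understated, and where all 5 arrays of a group lay at the floor the difference is given as a bound. Such a bound leaves out sampling error. The floor also removes the spread of arrays that lie at it, so p-values there may be too small. Arrays give no counting depth, and the number of arrays limits the precision: the median residual SD was 0.18 on the log2 scale.

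Probe sets were named from the platform annotation, with symbols updated by gene ID through a RefSeq gene table of assembly GRCm38.p6. Of the 9977 probe sets, 8724 had 1 symbol, 346 had several and 907 had none. Of those with 1 symbol, 8708 were matched by gene ID and 0 symbols changed. No gene was named from a probe set with several symbols. The array files name no genome build, so no coordinates are given, and the RefSeq table served for names, chromosomes and neighbouring genes.

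Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), 5 Scd1-null against 5 wild-type arrays with no covariate, and p-values were Benjamini-Hochberg adjusted over the kept probe sets. A probe set with an adjusted p under 0.05 was called. All tests were two-sided. For single measures an exact permutation test over the 252 assignments of 5 arrays was used, whose smallest possible p is 0.00794. For gene lists, each gene was represented by its probe set of highest mean. Lists with at least 4 measured members were tested with camera at a preset correlation of 0.01, adjusted over all 30 lists, of which 20 were processes and 10 were markers of cell types. The same lists were tested with an estimated correlation and with fry. These steps used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 for reading tables and drawing.

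The genes to name were chosen by a rule fixed before the data were examined. It took the Scd family, then per direction the 15 genes with the largest difference among called probe sets whose groups did not overlap. It added up to 4 called members of each process list by smallest p, or all of them where there were 5 or fewer. Srebf1, Fasn, Gpam, Acaca, Cpt1a, Acadvl, Ppara, Fgf21 and Nnt were among those to be named whether called or not, and 1 more is not reported here. Of these Acaca, Acadvl and Fgf21 had no kept probe set. The rule named 62 genes.

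The procedure was tested on simulated data for this comparison, with 200 probe sets changed and 7673 kept. Of changes of 0.5 on the log2 scale 56.1% were recovered, of changes of 1 88.7%, and of changes of 2 95.2%. Of the 159 calls 7 were false. The percentages are over the 66, 62 and 63 changed probe sets that were kept. Values were drawn independently for each probe set. Correlation between genes, fluidics run, chip lot and outlying arrays were thus not simulated.

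Alternatives fixed beforehand were the deposited scale, scaling to the 75th percentile, floors at the 10th and 40th percentiles, a pseudocount of 16 in place of the floor, no filter or a filter at the median, eBayes without trend or robust, array weights, the replicate number as a block, the fluidics run as a block, the mean over a gene's probe sets, leaving out chromosome 19, and leaving out each array in turn. Added after seeing the data were the fluidics module as a block, the run as a random block, run 2 alone, cyclic loess, leaving out wild-type replicates 3 and 4 together, and leaving out the member of the largest difference from each called list.

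By the times of hybridisation the 10 arrays fell into 3 fluidics runs on 1 day. Run 1 held Scd1-null replicates 1 to 4, run 2 held Scd1-null replicate 5 with wild-type replicates 1, 2 and 3, and run 3 held wild-type replicates 4 and 5. All Scd1-null arrays came from lot A and all wild-type arrays from lot B, so chip lot and genotype cannot be told apart.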

Results

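Liver transcripts were measured on 10 arrays, 1 per mouse, from 5 mice without a working Scd1 gene and 5 wild-type mice. Scd1 encodes stearoyl-CoA desaturase 1, the enzyme that makes monounsaturated fatty acids from saturated ones. The study asked which liver genes are expressed differently when Scd1 is lost, on chow and without fasting. Median intensity was 840 ± 12.9 (SD, n = 5) on the Scd1-null arrays and 814 ± 23.1 (SD, n = 5) on the wild-type arrays before normalization. Between 73.8% and 75.7% of probe sets lay above the floor on each array. The floor was set at the 25th percentile of all values, so shares of about this size follow from it and are not a detection rate. The Scd1-null mice carried a mixed 129 and C57BL/6J background and the wild-type mice were C57BL/6J, and chip lot divided the arrays in the same way, so each difference below is one of genotype, background and lot together. Single arrays are named null 1 to null 5 and WT 1 to WT 5 by their replicate numbers.

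Scd1 itself separated every Scd1-null liver from every wild-type liver. Its brightest probe set read 17520 ± 2613 (SD, n = 5) in wild type and 483 ± 247 (SD, n = 5) in Scd1-null liver. Scd1 fell by 5.28 on the log2 scale (SE 0.23, limma adjusted p = 4.31e-08), a 38.9-fold difference, with an exact permutation p = 0.00794. The highest Scd1-null value was 919, on null 4, and the lowest wild-type value was 13370, on WT 4. Of the 5 Scd1-null arrays 3 lay at the floor, so the fold is an understatement. A second Scd1 probe set fell by 5.18 (adjusted p = 1.19e-06). The third lay near the floor in both groups, with a difference of 0.07 (adjusted p = 0.714). Scd2, a related desaturase, was at or near the floor on all arrays and was not tested. The part of Scd1 that was disrupted is not given in the sources used here, so the loss of signal checks the labels only as far as these probes reach it.

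**Figure D1:**
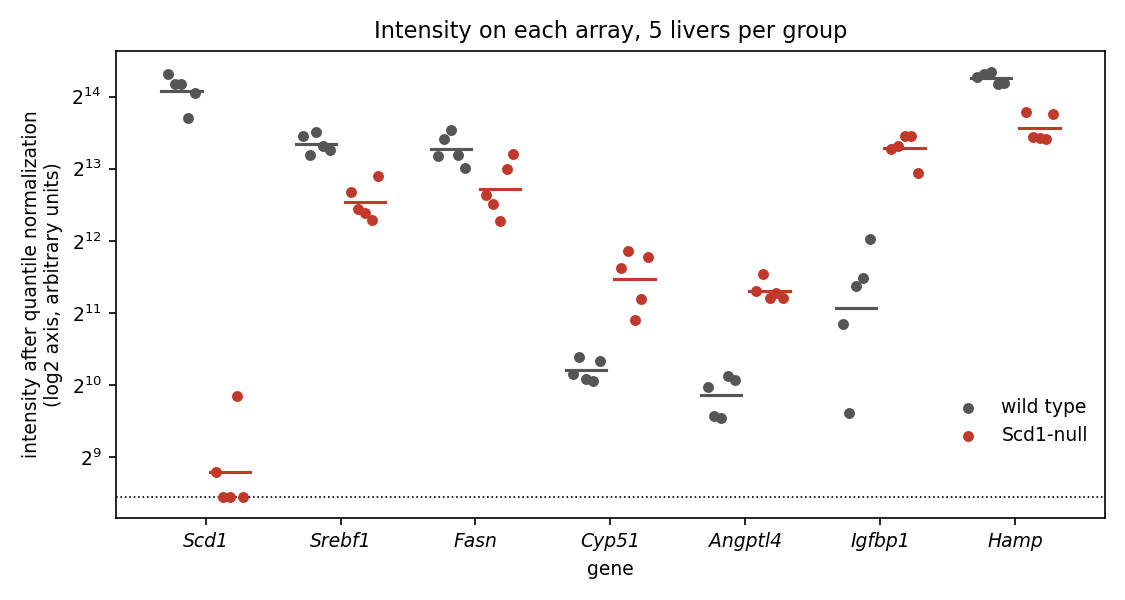
Intensity of 7 genes on each array after quantile normalization (log2 axis, arbitrary units), with wild-type livers in grey and Scd1-null livers in red; each point is 1 array, each horizontal bar the mean of the log2 values of 5 arrays, and the dotted line the floor of 351. The Scd1-null points for Scd1 lie at or below 919, against 13370 or more in wild type, and those for Fasn overlap between the groups. Each gene is drawn at 1 probe set. Angptl4 and Igfbp1 are drawn where their log2 differences were largest, at 1.45 and 2.22. Probe sets not drawn gave 0.39 and 0.08 for Angptl4 and -0.50 for Igfbp1.

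Over all genes, 270 probe sets were higher and 209 lower in Scd1-null liver, of 7569 tested with limma, and the lower ones include 2 of Scd1. They stood for 239 genes higher and 183 lower, and 1 gene was called both ways. The higher calls had a median difference of 0.54 and the lower ones a median of -0.43 on the log2 scale. At least 2-fold differences were fewer, with 17 probe sets higher and 10 lower. In 367 of the 479 calls all 5 Scd1-null values lay on one side of all 5 wild-type values. Among all kept probe sets 615 did so, or 8.13%, where chance gives 0.794%. Of all calls 56.4% were higher. On the deposited scale the same comparison called 480 probe sets higher and 96 lower, or 83.3% higher, so the balance between the directions rests on the normalization.

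The fluidics run limits these counts. Run 1 held Scd1-null arrays alone and run 3 wild-type arrays alone. With the run as a block, each difference of a gene or list thus comes from null 5 against WT 1, 2 and 3. That setting and run 2 alone are therefore not separate checks of sign or size. With the run as a block 7 probe sets were called higher and 7 lower, and within run 2 alone, which held 1 Scd1-null and 3 wild-type arrays, 0 were higher and 1 lower by limma, with 1300 probe sets at an unadjusted p under 0.05. Of the 479 probe sets of smallest p in runs 1 and 3 alone, 84.1% had the same sign in run 2, at 63.7% of the median size. Of the 58 named genes that were called, Scd1, Angptl4 and Cebpb passed with the run as a block, and Scd1 alone within run 2. With the run as a block all 58 had the same sign and 46 stayed within 1.5 times their log2 size, while the median standard error of all calls rose from 0.111 to 0.199. Run 2 took part in picking these calls, so their sign and size there are not an independent test. Of the other 12 genes 7 were smaller, with values given below, and 5 larger: Cebpb 1.45, Nsdhl 0.65, Slc25a20 -1.74, Usp18 -1.35 and Pik3ca -0.58.

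Single arrays moved the counts of 270 higher and 209 lower as well. Without null 1, null 2 or null 5 they were 143, 102 and 126 higher and 110, 62 and 79 lower, and without null 3 136 were lower. Without WT 1, WT 2 or WT 3 they were 156, 176 and 132 higher and 82, 91 and 88 lower. Without WT 4, the array that stood apart on the second principal component (15% of the variance), they were 491 and 449.

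Igfbp1 had the largest difference among the higher calls. Igfbp1, which encodes a binding protein for insulin-like growth factors, rose by 2.22 on the log2 scale (SE 0.33, adjusted p = 0.00375), from a geometric mean intensity of 2152 to 9998. The gene's other probe set went the other way, at -0.50 (adjusted p = 0.0473), so the direction for Igfbp1 depends on the probe set. That lower call was lost without null 1, 2, 4 or 5 (0.0696 to 0.109) or WT 1, 3 or 5 (0.0715 to 0.103). Ddit4, an inhibitor of mTOR signalling, was at the floor on all 5 wild-type arrays and at least 3.42-fold higher in Scd1-null liver (adjusted p = 0.0099). Slc38a2, an amino acid transporter, rose by 1.60 (adjusted p = 0.00065). Angptl4, a secreted inhibitor of lipoprotein lipase, rose by 1.45 at 1 of its 3 probe sets (adjusted p = 0.000109), by 0.39 at the brightest (adjusted p = 0.0245), and differed by 0.08 at the last (adjusted p = 0.674). The call at the brightest was lost without null 2, 3 or 5 (0.07, 0.051 and 0.0552) or WT 2 (0.0546). Erbb3 rose by 1.28 (adjusted p = 0.00375), with -0.23 at its other probe set (adjusted p = 0.235).

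Further genes were higher by smaller amounts. Nfkbia, an inhibitor of NF-kappaB, rose by 1.08 (adjusted p = 0.00311), and by 0.33 at its brighter probe set (adjusted p = 0.0292). That second call was lost without null 1, 2, 3 or 5 (0.0518 to 0.077) or WT 1, 2 or 3 (0.0593 to 0.0665). Cebpb, a transcription factor of the acute phase response, rose by 0.93 (adjusted p = 0.0144). Tpmt rose by 1.17, Rsrp1 by 1.20, Lap3 by 1.09, Car8 by 1.06, Mcpt1 by 1.06 and Retreg1 by 1.05. Ell2 rose by 0.98 at 1 of its 3 probe sets (adjusted p = 0.0131), and the others gave 0.78 (adjusted p = 0.0604) and 0.17 (adjusted p = 0.494). The former passed without WT 4 (0.0178) or WT 5 (0.0469). Mcpt1 was at the floor on 2 wild-type arrays and Ell2 on 1. Dsc2 was at the floor on all 5 wild-type arrays and at least 2.03-fold higher at 1 probe set, but differed by 0.13 at the other (adjusted p = 0.465).

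Apart from Scd1, the lower calls had smaller sizes. Srebf1, which encodes the transcription factor that drives fatty acid synthesis genes, fell by 0.81 on the log2 scale (SE 0.11, adjusted p = 0.00271), from a geometric mean intensity of 10420 to 5957. The Srebf1 value was -0.49 with the run as a block (adjusted p = 0.201). Hamp, which encodes the iron-regulating hormone hepcidin, fell by 0.70 (adjusted p = 0.00121). G0s2, an inhibitor of the lipase that breaks down stored fat, fell by 0.75 (adjusted p = 0.0144). The chaperone genes Dnajb9 and Bag3 fell by 1.10 (adjusted p = 0.00614) and by 0.88 (adjusted p = 0.00743). Dnajb9 was at the floor on 4 Scd1-null arrays. Angpt2 fell by 0.79 (adjusted p = 0.0252), and that call was lost without null 1 (0.0592), null 2 (0.0532) or WT 1 (0.0602). Angpt2 was at -0.37 with the run as a block (adjusted p = 0.615). Rps13 fell by 0.75, Dnah8 fell by 1.11, Mip fell by 0.98 and S100a14 fell by 0.80. S100a14 was at the floor on 4 Scd1-null arrays, and Dnah8 and Mip were on 2 each. Ibsp fell by 0.74, a call lost without null 2 (adjusted p = 0.0555). Wfdc18 fell by 0.70, a call lost without null 2 (0.0555), WT 2 (0.0529) or WT 3 (0.0505). Dnah8, Dnajb9, Mip, S100a14, Ibsp and Wfdc18, and the higher Lap3, Mcpt1 and Dsc2, were dim in both groups. At the probe sets given, their mean log2 values lay between 8.455 and 9.965. By comparison, 72 measured genes of families restricted to other tissues averaged 9.985 in Scd1-null and 10.056 in wild type. Whether such dim signal comes from the named transcripts was not tested.

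**Figure D2:**
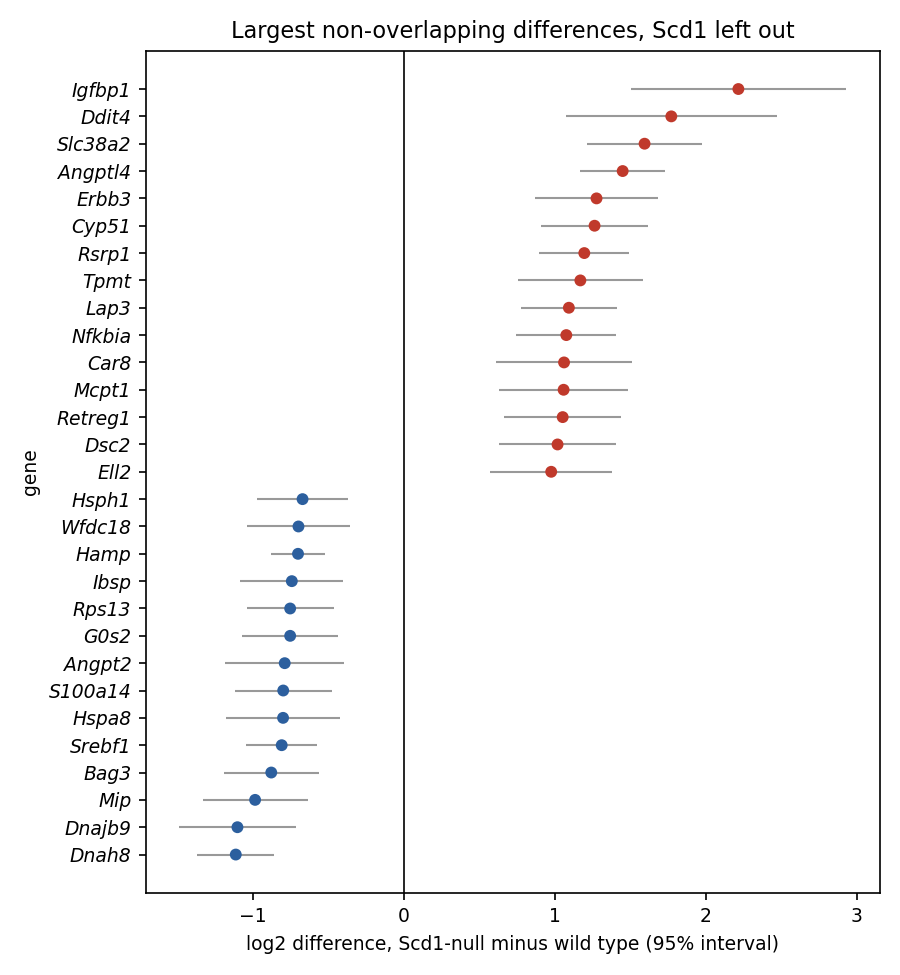
Log2 difference between Scd1-null and wild-type liver (Scd1-null minus wild type) for 29 genes other than Scd1, the largest differences per direction among called probe sets whose groups did not overlap; points are estimates from 5 arrays per group and lines are 95% intervals. Igfbp1 lies at 2.22 and Dnah8 at -1.11. Each gene is drawn at 1 probe set, and the other probe set of Igfbp1, not drawn, gave -0.50.

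Lipid synthesis was read through 2 lists, 1 for fatty acids and triglycerides and 1 for cholesterol. In the lipogenesis list 14 genes were measured, of which 0 rose and 1 fell, Srebf1, and 4 fell when p was adjusted over the list alone. Fasn, fatty acid synthase, had a difference of -0.55 (adjusted p = 0.0551) and passed without null 4 (0.0497), null 5 (0.0331), WT 4 (0.0475) or WT 5 (0.0465). Gpam, which starts triglyceride synthesis, had a difference of 0.15 (adjusted p = 0.398). The list's median was -0.10, but 0.04 on the deposited scale, and camera gave adjusted p = 0.277. In the cholesterol synthesis list 13 genes were measured, of which 3 rose and 0 fell, and 4 rose when adjusted over the list alone. The 3 called over all probe sets were Cyp51, a sterol demethylase, which rose by 1.26 (adjusted p = 0.00255), Fdft1, squalene synthase, by 0.44 (adjusted p = 0.0278) and Nsdhl by 0.42 (adjusted p = 0.0322). The Fdft1 call was lost without null 2 (0.0775), null 5 (0.065), WT 1 (0.0603) or WT 3 (0.0612). The Nsdhl call was lost without null 1, 2 or 5 (0.0577, 0.07 and 0.0789) or WT 1, 3 or 5 (0.0792, 0.0555 and 0.053). Nsdhl's other probe sets gave 0.55 (adjusted p = 0.0545), which passed without null 3 (0.0403), WT 2 (0.0359) or WT 4 (0.0389), and 0.43 (adjusted p = 0.0499), which was lost without null 2, 3, 4 or 5 (0.0851 to 0.117) or WT 1, 2, 3 or 5 (0.0607 to 0.109). The list's median was 0.38 and camera gave adjusted p = 0.000573, but adjusted p = 0.412 with an estimated correlation. The cholesterol synthesis median was 0.51 with the run as a block, which rests on 1 Scd1-null array.

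Fat oxidation was read in mitochondria and in peroxisomes. Of 14 measured genes of mitochondrial fatty acid oxidation 2 rose and 1 fell, and when adjusted over the list alone 5 rose and 1 fell. Etfdh rose by 0.48 (adjusted p = 0.00924) and Acadl by 0.46 (adjusted p = 0.0357). Slc25a20, the carnitine carrier, fell by 1.13 (adjusted p = 0.0318), with overlapping groups. The Acadl call was lost without null 1, 2 or 5 (0.0804, 0.0958 and 0.0688) or WT 1, 2 or 3 (0.061, 0.0651 and 0.0844). The Slc25a20 call was lost without null 1, 2 or 5 (0.0747, 0.0837 and 0.0808) or WT 1, 2, 3 or 5 (0.0587, 0.0712, 0.0804 and 0.0531). Cpt1a, the entry step, differed by 0.02 (adjusted p = 0.938, 95% interval -0.26 to 0.30), and camera gave adjusted p = 0.244 for the list (0.0472 with scaling to the 75th percentile).

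In the list of peroxisomal oxidation and PPAR alpha targets 20 genes were measured, of which 3 rose and 0 fell, and 4 rose when adjusted over the list alone. Besides Angptl4, whose values at each probe set are given above, Hsd17b4 rose by 0.48 (adjusted p = 0.00743) and Cyp4a10 by 0.69 (adjusted p = 0.0101), but Cyp4a10 was at 0.26 with the run as a block (adjusted p = 0.518). Ppara itself differed by 0.11 (adjusted p = 0.47). The median was 0.08 and camera gave adjusted p = 0.0322, but adjusted p = 0.417 with an estimated correlation. With the run as a block the median turned to -0.04 (camera adjusted p = 0.748). The call was also lost without null 1 (0.0679), null 2 (0.0764), null 3 (0.141), WT 3 (0.111) or WT 5 (0.0697). Cyclic loess (0.0638), array weights (0.0679), leaving out wild-type replicates 3 and 4 together (0.0694), leaving out the member of the largest difference (0.0651) and fry (0.124) ended it too.

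Amino acid catabolism and energy metabolism held 3 of the 5 called lists. Of 21 measured genes of amino acid catabolism and the urea cycle 4 rose and 0 fell, and 7 rose when adjusted over the list alone. Hgd rose by 0.58 (adjusted p = 0.00375), Glud1, glutamate dehydrogenase, by 0.60 (adjusted p = 0.00826), Agxt by 0.33 (adjusted p = 0.0207) and Hal by 0.45 (adjusted p = 0.0421). The Agxt call was lost without null 1, 2 or 5 (0.0511, 0.0633 and 0.0521) or WT 1 or 3 (0.0501 and 0.0541). The Hal call was lost without any 1 null array (0.0506 to 0.0923) or without WT 1, 2 or 3 (0.0971, 0.0878 and 0.101). The median was 0.12 and camera gave adjusted p = 0.000573, but adjusted p = 0.412 with an estimated correlation. The median was 0.19 with the run as a block, which rests on 1 Scd1-null array.

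Of 30 measured genes of oxidative phosphorylation 3 rose and 0 fell, and 8 rose and 1 fell when adjusted over the list alone. Cycs, cytochrome c, rose by 0.46 (adjusted p = 0.0151), Sdha by 0.39 (adjusted p = 0.0293) and Atp5a1 by 0.26 (adjusted p = 0.0288). The Sdha call was lost without null 1, 2 or 5 (0.0691, 0.0664 and 0.0812) or WT 1, 2 or 3 (0.07, 0.064 and 0.0684). The Atp5a1 call was lost without any 1 null array (0.0513 to 0.0711) or without WT 1 or 3 (0.0715 and 0.0665). The median was 0.12 and camera gave adjusted p = 0.00267, but adjusted p = 0.412 with an estimated correlation. In the list of gluconeogenesis and glycolysis 9 genes were measured and Igfbp1 alone was called, both over all probe sets and when adjusted over the list alone. The median was 0.10 and camera gave adjusted p = 0.017, but adjusted p = 0.412 with an estimated correlation, and adjusted p = 0.0988 without Igfbp1. The call ended with cyclic loess (0.0638) and within run 2 (0.0812). With the run as a block, which rests on 1 Scd1-null array, the medians of oxidative phosphorylation and of gluconeogenesis and glycolysis were 0.21 and 0.14. Camera called 5 of the 30 lists, the 5 named with a call here.

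**Figure D3:**
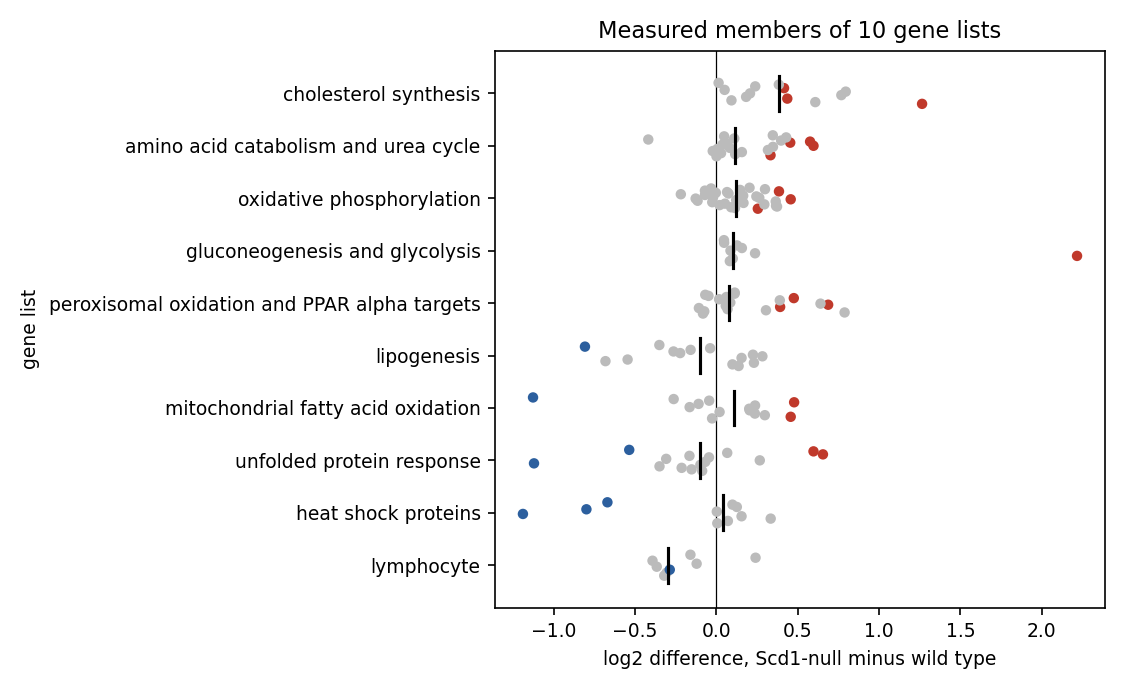
Log2 difference between Scd1-null and wild-type liver of each measured member of 10 gene lists, 1 point per gene at its brightest probe set; red points were called higher, blue points called lower and grey points not called, and black bars are list medians. Cholesterol synthesis has a median of 0.38, lipogenesis of -0.10, and the far point of gluconeogenesis and glycolysis is Igfbp1.

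Protein folding was read through 2 lists. In the unfolded protein response list 2 of 15 measured genes rose and 2 fell, and 2 rose and 4 fell when adjusted over the list alone. The disulfide isomerase genes Pdia3 and Pdia6 rose by 0.66 (adjusted p = 0.00336) and by 0.60 (adjusted p = 0.0129). Pdia6's other probe sets gave 0.74 (adjusted p = 0.0159) and 0.45 (adjusted p = 0.0662), the latter passing without null 4 (0.0369). Dnajb9 fell by 1.12 at its brightest probe set (adjusted p = 0.0228), and Xbp1, a transcription factor of that response, fell by 0.54 (adjusted p = 0.0175). That Dnajb9 call was lost without null 1, 2 or 5 (0.055, 0.0612 and 0.0556) or WT 1 (0.055). Xbp1 was at -0.27 with the run as a block (adjusted p = 0.494). Camera gave adjusted p = 0.589. Of 10 measured heat shock genes 3 fell, over all probe sets and when adjusted over the list alone: Hspa8 fell by 0.80 (adjusted p = 0.0209), Hsph1 fell by 0.67 (adjusted p = 0.0177) and Hspa1b fell by 1.19 (adjusted p = 0.0464), the last with overlapping groups. The Hspa8 call was lost without WT 1 (0.054). The Hspa1b call was lost without any 1 null array (0.0549 to 0.103) or without WT 1, 2 or 5 (0.0865, 0.086 and 0.0562), and Hspa1b was at -0.74 with the run as a block (adjusted p = 0.532). The list's median was 0.04, its mean -0.19 and its camera direction down (adjusted p = 0.823), so these differ in sign.

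In the other process lists at most 2 members were called. Lpl, lipoprotein lipase, rose by 0.77 (adjusted p = 0.0233) as the 1 called gene of 16 that handle lipoproteins, a call lost without null 2 (0.0521), WT 2 (0.0526) or WT 3 (0.0573). Lpl was at 0.31 with the run as a block (adjusted p = 0.624). Aldh1a1 rose by 0.43 (adjusted p = 0.0355) and Gstp1 by 0.37 (adjusted p = 0.0464) among 29 genes of xenobiotic metabolism. The Aldh1a1 call was lost without any 1 null array (0.0533 to 0.0866) or without WT 1 or 3 (0.07 and 0.0691). The Gstp1 call was lost without any 1 null array (0.0521 to 0.107) or without WT 1, 3, 4 or 5 (0.0572, 0.105, 0.0503 and 0.0741). Cyp17a1, of the female-biased list, rose by 0.59 (adjusted p = 0.0275), a call lost without null 1, 3, 4 or 5 (0.0517 to 0.0634) or WT 1 or 2 (0.0678 and 0.0648). Cyp17a1 lies 2.27 Mb from Scd1, so alleles linked to Scd1 may contribute to its difference. That was not tested for this gene. In the male-biased list, which also holds Gstp1, the median was 0.35, and 4 of 6 members rose and 1 fell when adjusted over the list alone. In the female-biased list the median was -0.11, and Cyp17a1 alone passed when adjusted over the list alone. Serpina1e, the male-biased member that fell, fell by 0.27 (adjusted p = 0.0278), a call lost without null 1, 2 or 5 (0.0606 to 0.0647) or WT 1, 2 or 3 (0.0622 to 0.0691).

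Pik3ca, of insulin signalling, fell by 0.39 (adjusted p = 0.0287), a call lost without null 2, 3 or 5 (0.0597 to 0.077) or WT 1, 2 or 3 (0.0593 to 0.07), and its other probe set gave -0.12 (adjusted p = 0.539). Cry1, of the clock list, fell by 0.51 (adjusted p = 0.0447), a call lost without null 2, 3, 4 or 5 (0.0609 to 0.0831) or WT 1, 2, 3 or 5 (0.0503 to 0.096). Usp18, of the interferon response, fell by 0.70 (adjusted p = 0.0466), a call lost without null 2, 4 or 5 (0.0836 to 0.111) or WT 1, 2, 3 or 5 (0.0595 to 0.103).

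Camera called none of these lists, though other settings called some of them. Xenobiotic metabolism had adjusted p = 0.261, but 0.0122 on the deposited scale and 0.00927 with scaling to the 75th percentile. The interferon response had 0.173, but 0.0277 on the deposited scale. Insulin signalling had 0.241 and the antioxidant response 0.173, where fry gave 0.0184 and 0.0475. Camera adjusted p was 0.753 for lipoprotein handling, 0.417 for bile acids, 0.965 for the cell cycle, 0.71 for the acute phase response, 0.924 for the clock, and 0.924 and 0.244 for female-biased and male-biased liver genes. Of the 12 measured genes of bile acid synthesis and transport, the 10 of the antioxidant response and the 12 of the cell cycle 0 were called by limma, with 3, 3 and 2 at an unadjusted p under 0.05.

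Markers of 10 cell types were read for a difference in the make-up of the tissue. Of 8 measured lymphocyte markers 1, Cd4, fell, by 0.29 (adjusted p = 0.0421), and 4 fell and 1 rose when adjusted over the list alone. Cd4 was chosen after its values were seen, and its call was lost without null 2, 3, 4 or 5 (0.069 to 0.099) or WT 1, 2 or 3 (0.057 to 0.0993). The lymphocyte median was -0.30, with camera adjusted p = 0.0988, or 0.037 without WT 2, 0.0442 with a floor at the 10th percentile and 0.0167 with the mean over a gene's probe sets, and fry adjusted p = 0.0184. Camera adjusted p was 0.483 for hepatocyte markers, 0.173 for macrophages, 0.821 for neutrophils, 0.294 for stellate cells, 0.277 for endothelium, 0.924 for cholangiocytes, 0.71 for erythroid cells, 0.965 for adipocytes and 0.924 for exocrine pancreas, with 0 members called in each by limma and 6 of 61 at an unadjusted p under 0.05. Adjusted over the list alone, 1 neutrophil and 1 stellate marker fell. The adipocyte median was -0.02 where its camera direction was up, and the median was 0.12 on the deposited scale, 0.03 with scaling to the 75th percentile and 0.01 with cyclic loess.

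Some measures of array and RNA quality differed between the groups. The ratio of the 3' to the 5' control probe set of Pcx was 1.63 ± 0.161 (SD, n = 5) on Scd1-null and 1.16 ± 0.207 (SD, n = 5) on wild-type arrays (exact permutation p = 0.0159). The same ratio was 0.959 ± 0.0454 and 0.907 ± 0.0387 for actin (exact permutation p = 0.0714), and 0.838 ± 0.0408 and 0.871 ± 0.0553 for Gapdh (exact permutation p = 0.317). The 5' probe set of 18S ribosomal RNA read 1527 ± 459 on Scd1-null and 4505 ± 3010 on wild-type arrays (exact permutation p = 0.0238). The trimmed mean before normalization was 1557 ± 50.4 and 1441 ± 71.5 (exact permutation p = 0.0317).

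Nnt, which carries a deletion in the C57BL/6J strain, rose by 0.33 (adjusted p = 0.0421) in the mixed-background Scd1-null livers. The call was lost without any 1 null array (0.0645 to 0.08) or without WT 1, 2 or 3 (0.0819, 0.0746 and 0.0763), and Nnt was at 0.22 with the run as a block (adjusted p = 0.567).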

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

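The tests of fasting genes, glucocorticoid genes and clock genes were chosen after the results were seen, as were the test of fluidics run that picks probe sets in runs 1 and 3 and the reading of the count without chromosome 19 as a test.

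In 7 of 133 groups of 5 arrays, over the named genes and the measures of array quality, 1 array stood far from the other 4, where chance gives about 1 in 20 groups, or 6.7. Groups with 3 or more arrays at the floor were not tested. Scd1-null replicate 2 read 2980 for Angptl4 against 2371 to 2533, and 4732 for Fdft1 against 3816 to 4041. Scd1-null replicate 3 read 1030 for Hsph1 against 1386 to 1561. Scd1-null replicate 5 read 3449 for Nsdhl against 2614 to 2790, and 5465 for Gpam against 3834 to 4209. Scd1-null replicate 4 read 3085 for Pdia6 against 3704 to 3983. The 3' to 5' ratio of Gapdh was 0.908 in Scd1-null replicate 1 against 0.807 to 0.832. Among the 66 control probe sets, which enter no comparison, the 5' probe set of the mouse transferrin receptor read 7809 on Scd1-null replicate 4 and 399 to 649 on the other arrays, a difference that was not tested.

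The first pattern is the number of probe sets called between the groups. The real split called 479 and the highest of 99 others 3, and per direction 270 and 209 against at most 2. Only 1 of 100 splits, the real one, reached each of the 3 counts, so a chance division of the arrays is unlikely. Each other split mixed both groups, so its low count is not that of 2 groups that are alike. Some measures of array and RNA quality differed between the groups, as given above, and their part in the calls was not tested. Chip lot cannot be told apart from genotype, because 0 lots held both groups. The fluidics run cannot be told apart either: the median of the calls was 0.53 in run 2 against 0.50 over all arrays, past the bound set beforehand, but that bound was wrong because run 2 had helped to pick those calls. So the 479 probe sets of smallest p in runs 1 and 3, where 16 were called, were read in run 2, where 63.7% of their median size was left and 84.1% had the same sign, on 1 Scd1-null array. Strain away from the locus may contribute, with Nnt higher by 0.33 in a fragile call. With chromosome 19 left out 456 probe sets were called, so most calls lay outside it. That count cannot weigh 129 alleles linked to Scd1. It kept 7338 of the 7569 probe sets, so most calls would have stayed whatever the cause. Nor does it cover effects of such alleles on genes elsewhere. Genes near Scd1 leave them open too: 8 of 91 genes within 20 Mb, Cyp17a1 among them, were called, or 8.79%, against 6.35% of others. The odds ratio was 1.42 (Fisher's exact p = 0.382, 95% interval 0.589 to 2.96). The loss of Scd1 itself stays open as well.

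The second pattern, picked after its values were seen, is the higher level of Ddit4, of Angptl4 at 2 of its 3 probe sets and of Igfbp1 at 1 of its 2 (the other was called lower, so its direction is not settled), grouped here as stress-linked as a hypothesis. Time of day of tissue collection stays open. Arntl, Clock and Npas2 minus Per1, Per3, Nr1d1 and Nr1d2 gave 0.134 (95% interval -0.154 to 0.421, exact permutation p = 0.349). Both sets thus did not move apart by the bound of 0.5, but that bound was set after the results were seen. Npas2 at 0.64 (adjusted p = 0.0581) and Nr1d2 at 0.50 (adjusted p = 0.0576) lay on the same side, so they partly cancelled in the difference. Cry1, which the difference leaves out, fell by 0.51 (adjusted p = 0.0447) in a fragile call. The labels say that the mice were not fasted, and the values do not settle fasting or low insulin, since Pdk4, Cpt1a, G6pc, Irs2, Cyp4a14 and Acot1 differed by 0.176 on average (95% interval -0.235 to 0.587, exact permutation p = 0.365). Glucocorticoids stay open too, with 14 induced genes at 0.065 (95% interval -0.11 to 0.24, exact permutation p = 0.413), of which Klf9 was called at 0.35 (adjusted p = 0.0482), a call lost without Scd1-null replicate 1, 2, 4 or 5 (0.0635 to 0.115) or wild-type replicate 1, 2, 3 or 4 (0.0535 to 0.0899).

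The third pattern is the number of gene lists called. Camera called 5 lists and the highest of the other splits called 8, and 10 of the 100 splits called 5 or more, so chance cannot be excluded for it.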

How the results depend on the processing

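The settings named as added in the processing account were chosen after the data were seen. Scd1 was called under each of its 27 alternatives, between -5.77 and -4.72 on the log2 scale, with adjusted p up to 0.00358, and between -5.54 and -5.20 when 1 array was left out. The 270 probe sets higher and 209 lower became 480 and 96 on the deposited scale, 517 and 497 with array weights, 7 and 7 with the fluidics run as a block and 0 and 1 within run 2, by limma. The probe sets at an unadjusted p under 0.05, 1966 over all arrays, were 1188 with the run as a block and 1300 within run 2. Without the filter on dim probe sets, which adds probe sets to the adjustment, 152 were higher; the module as a block gave 130 lower and the run as a random block 325 lower. With the replicate block 151 were higher and 68 lower, though the replicate numbers do not pair the mice. After each group's mean was taken off every probe set, same-numbered arrays correlated between -0.127 and 0.108. By those values 1 of the 5 numbers matched its own best. Leaving out 1 array gave 102 to 491 higher and 62 to 449 lower. The 5 lists became 3 with cyclic loess, 3 within run 2, 0 with an estimated correlation and 4 to 6 when 1 array was left out. Of the 58 named calls 36 held whichever array was left out, 22 were lost without the filter, 55 with the run as a block and 57 within run 2. With the run as a block all 58 had the same sign and 46 stayed within 1.5 times their log2 size, while the median standard error of all calls rose from 0.111 to 0.199. Both settings take their differences from run 2 alone, with 1 Scd1-null and 3 wild-type arrays, so they are not separate checks. Beyond that design and the larger standard error, the cause of the lost calls was not tested. Signal near the floor limits genes such as Dnajb9 and Dsc2, whose differences are understated.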

Other observations

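The families here were chosen after the values were seen, as were the tests of tissue-restricted and immune genes. Values on the deposited scale stand beside medians that it turned in sign or moved by over 1.5 times.

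Of 37 measured subunits of the proteasome, which degrades tagged proteins, 6 were called higher, Psma3, Psme4 and Psmd14 among them, and 0 lower, with a median of 0.12 on the log2 scale (0.26 on the deposited scale) and 28 above 0. Camera gave adjusted p = 0.00147 over 12 families, but adjusted p = 0.32 with an estimated correlation. Of 8 aldehyde dehydrogenases 3 were called higher, Aldh2 among them, with a median of 0.32 (camera adjusted p = 0.0111, but adjusted p = 0.265 with an estimated correlation). Of 55 mitochondrial ribosomal proteins 2 were called higher and 1 lower, with a median of 0.09, or 0.18 on the deposited scale (camera adjusted p = 0.0113, but adjusted p = 0.32 with an estimated correlation). Of 31 Rab GTPases 4 were called higher, Rab18 among them, with a median of 0.12, or 0.20 on the deposited scale (camera adjusted p = 0.0342, but adjusted p = 0.32 with an estimated correlation). Of 21 genes of ER translocation and N-glycosylation 3 were called higher, with a median of 0.08, or 0.16 on the deposited scale (camera adjusted p = 0.0366, but adjusted p = 0.348 with an estimated correlation). Of 25 genes of the major histocompatibility complex 2 were called lower, with a median of -0.09, but 0.05 on the deposited scale (camera adjusted p = 0.0473, but adjusted p = 0.32 with an estimated correlation). Of 30 cytosolic ribosomal proteins 1 was called, Rps13, lower, with a median of -0.001, but 0.17 on the deposited scale (camera adjusted p = 0.674). The genes named here were called whichever array was left out. Each other call in these families was lost without Scd1-null replicate 2 or 5, at least, with adjusted p up to 0.119.

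Reading the lower calls gave the impression that they lie mostly among dim probe sets. The measurement went against it: 50 of the 209 lower calls, or 23.9%, lay in the dimmest of 3 equal groups of probe sets, against 24.8% of the higher calls. The values computed for that impression are given without weighing it. Genes of families restricted to other tissues, 72 measured, differed by -0.071 on average (95% interval -0.167 to 0.025, exact permutation p = 0.135). Lymphocyte, macrophage and neutrophil markers, 24 measured, differed by -0.146 (95% interval -0.289 to -0.002, exact permutation p = 0.00794, the smallest possible), with all 5 Scd1-null livers below all 5 wild-type livers.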
